A study of Capra hircus with 90 samples.

How the data were processed

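Bulk RNA was sequenced from punches of frozen brainstem of adult outbred female goats. There were 5 exposure groups of 6 goats: 24 h in room air, 3 h in 6% CO2, 24 h in 6% CO2, 7 d in room air and 7 d in 6% CO2. Each goat gave a punch at 3 sites, which makes 15 groups of 6 libraries and 90 libraries in all. The nucleus of the solitary tract (NTS) was punched 0 to 2 mm rostral to the obex, the ventral respiratory column (VRC) 2 to 4 mm and the retrotrapezoid nucleus (RTN) 8 to 10 mm. Libraries were made with the SMART-Seq v4 and Nextera XT kits and read as 100-bp pairs. The 3 groups of the shorter exposures were extracted and sequenced in the first batch and both 7 d groups in the second, so the 24 h and 7 d groups differ in batch as well as in time.

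The authors' processing notes list fastp 0.24.0, STAR 2.7.10b, featureCounts 2.0.6 and edgeR 4.6. The genome build and annotation are not given in the sources used here. The deposited table holds raw counts per Ensembl goat gene for the 90 libraries, and 0 columns were left out. The authors also deposited gene tables for the CO2 comparisons, whose fold changes and mean abundances are log2 values per the file headers. No deposited entry had an absolute log2 change under 0.5, a limit that the counts of genes made here do not carry. The deposited likelihood ratio is a score, and the deposited PValue and FDR columns hold p-values.

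Gene symbols came from the authors' deposited tables, because the reference table used here held no Ensembl identifiers. A likelihood ratio fit over all 90 libraries with a minimum count of 5 in filterByExpr kept 17730 genes, the number implied by the deposited FDR values. Each of the 342 deposited entries matched exactly 1 gene of that fit by its mean abundance, with a largest difference of 0, and the 93 entries given as identifiers matched their own identifier. The largest difference in log2 fold change was 0.0015. This linked 238 symbols, all of genes the authors had selected on these same libraries, so a named gene is not independent evidence that CO2 acts on it. Genes without a linked symbol were tested and counted under their identifier.

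Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr on the groups, glmQLFit with legacy=FALSE and robust=TRUE, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons of CO2 with room air and of 24 h with 3 h of CO2 used that site's libraries of the same batch. Those of the 7 d effect with the 24 h effect used all 30 libraries of the site, from both batches. In all, 24 comparisons were made: 9 of CO2 with room air of the same site and batch, 3 of 24 h with 3 h of CO2, 3 of the 7 d effect with the 24 h effect, 3 of the effect between sites, and 6 between sites in room air. The 3 h goats have no room-air group of equal time and were compared with the 24 h room-air goats, as the study's design states. Fold changes are on the log2 scale with the standard error (SE) of the fit. Normalised counts (CPM) use TMM factors over all libraries and are given as mean ± SD.

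These comparisons, the threshold, the alternative settings, 29 gene lists and the naming rule were fixed before the data were examined. In each comparison of CO2 with room air the rule names the 12 rising and 12 falling genes of lowest p past 0.05 that have a symbol and a mean of at least 1 CPM. It adds members of the fixed lists past 0.05, at most 6 per list. Some further genes that the rule would name whatever their p are not linked to a symbol and are not analysed here. In comparisons of times and of effects the rule names the 5 of lowest p in each direction, and in comparisons across all 3 sites the 10 of lowest p. Other genes named were chosen after their values were seen, and the text says so. The planned competitive test of the lists needs the symbols of all genes and was not run. In its place a 1-sided Fisher's exact test counted list members in the deposited tables and among the genes called in the VRC at 24 h, over 348 pairs of list and table. All members of a list were taken as testable in it.

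Alternatives were DESeq2 1.42.0, RLE factors, no filter, a filter of 1 CPM in 6 libraries, other libraries in the fit, estimateDisp with legacy=TRUE, limma 3.58.1 voom with quality weights, a surrogate variable from sva 3.50.0, and the replicate number as a block. After the data were seen, fits without libraries that stood apart, without shallow libraries, without each library in turn and over all 90 libraries were added. The numbers 1 to 6 denote the same goat at each site: in 88 of 90 pairs of libraries the best correlation of residuals was with the same number. Residuals of the same number correlated at 0.0587 to 0.529, with a median of 0.286 against -0.0677 for other numbers. Goats of different exposures are different animals. Still, in the NTS residuals of the same number in room air and after 3 h correlated in all 6 pairs, at 0.104 or more. The median was 0.166, against -0.143 for other numbers, so divisions that part all 6 numbers were added there. Of the 6 room-air libraries 2 correlated best with their own number, and of the 6 libraries after 3 h 1 did. The number is thus not shown to pair these libraries. Numbers 1 to 4 of these groups correlated at 0.0756 to 0.290, numbers 5 and 6 at 0.256 to 0.586, and the 2 sets with each other at -0.350 to -0.123; what the number marks is not given in the sources used here. In no other pair of exposures of a batch at a site did all 6 pairs exceed 0.1. Each count was also compared with 100 divisions of the same libraries.

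Total counts per library ran from 5.46 M to 36.8 M with a median of 23.3 M, and 16482 to 18234 genes were detected. None of the 225 pairs of libraries of the same group duplicated each other by their counts; pairs across groups were not compared. The procedure was tested on simulated data with known changes: it recovered 12% to 46% of 1.5-fold changes and 64% to 90% of 2-fold changes. Differences below 1.5-fold were therefore mostly out of reach with 6 goats in a group. The simulated data held no set of libraries that stands apart and no genes that vary together. Recovery in the real libraries may therefore be lower than these shares.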

Results

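Transcript counts were obtained from 3 brainstem sites that take part in breathing and its control: the nucleus of the solitary tract (NTS), which receives chemoreceptor and lung afferents, the ventral respiratory column (VRC), which holds the rhythm generator, and the retrotrapezoid nucleus (RTN), which senses CO2. Each of 15 groups, made of 3 sites and 5 exposures, held 6 libraries. Mean totals per group lay between 18.9 M and 28.5 M counts. The shallowest libraries were 1 of the VRC after 24 h of CO2, with 5.46 M counts, and 1 of the NTS after 3 h of CO2, with 9.64 M. In the NTS of the first batch 5 libraries stood apart from the rest on the second principal component, which held 9.92% of the variance: numbers 5 and 6 of room air, 5 and 6 of 3 h and 5 of 24 h. All named genes carry a symbol because the authors chose them on these libraries, and CPM stands for TMM-normalised counts.

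The first question was what 3 h of 6% CO2 changed at each site. In the VRC, EGLN1, a prolyl hydroxylase that marks hypoxia-inducible factors for breakdown, and VEGFB, a growth factor of vessels, fell. EGLN1 fell by 0.82 on the log2 scale (SE 0.13, adjusted p = 0.0140), from 79.3 ± 9.8 to 44.6 ± 11.4 CPM (SD, n = 6 each). VEGFB fell by 0.89 (SE 0.14, adjusted p = 0.0140), from 32.3 ± 4.1 to 17.2 ± 3.6 CPM. Both falls are measured against the same VRC room-air libraries as the later falls at that site. Those libraries may stand apart from other room-air groups, as weighed below, and the falls at 3 h share that limit. The EGLN1 mean after 3 h was not below that of VRC room-air goats of the longer exposure, which are of another batch. In the RTN, THBD, the endothelial thrombomodulin that binds thrombin, rose by 1.81 (SE 0.29, adjusted p = 0.0250), from 3.0 ± 1.7 to 10.8 ± 3.2 CPM, and the unnamed ENSCHIG00000022219 fell by 2.09 (SE 0.33), from 9.36 to 2.22 CPM. By edgeR no other gene passed 0.05 at 3 h, which leaves 2 in the VRC, 2 in the RTN and 0 in the NTS. At an unadjusted p under 0.05 there were 1053 of 15605 genes in the NTS, 2006 of 15424 in the VRC and 1071 of 15479 in the RTN. By chance 780, 771 and 774 would be expected. Later counts of this kind likewise compare with a share of 0.05 of the genes tested. DESeq2 called 12, 121 and 17 genes at the NTS, VRC and RTN, and voom with quality weights called 1, 44 and 0.

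VEGFA, THBD, TUBB6, HYAL2 and NOS3 each had a log2 change of the same sign at all 3 sites after 3 h, and of these values only that of THBD in the RTN passed 0.05. In the VRC, THBD, TUBB6, HYAL2 and VEGFA came past it in 6, 5, 4 and 3 of 11 other settings, and in the NTS in 3, 4, 3 and 3 of 12. These genes, with ACVRL1 and VEGFC of the NTS, were chosen after their values were seen, so the likeness between sites is not a test. VEGFA, the main growth factor of vessels, differed by -0.64, -0.83 and -0.65 on the log2 scale in the NTS, VRC and RTN (SE 0.13, 0.16 and 0.16; adjusted p = 0.255, 0.0555 and 0.321). VEGFA averaged 47.1 ± 6.1, 55.7 ± 8.9 and 55.1 ± 7.9 CPM in room air and 30.1 ± 6.3, 31.5 ± 8.0 and 35.3 ± 8.4 CPM after 3 h (SD, n = 6 each). THBD differed by 1.59 in the NTS and 1.84 in the VRC (SE 0.35 and 0.32; adjusted p = 0.331 and 0.0529). TUBB6, a tubulin, differed by 1.01, 1.25 and 0.87, and HYAL2, a hyaluronidase, by 0.88, 0.86 and 0.45 in the NTS, VRC and RTN. NOS3, the endothelial nitric oxide synthase, differed by 0.95, 0.73 and 0.65. In the NTS, ACVRL1, an endothelial receptor of bone morphogenetic proteins, differed by 0.97 (SE 0.16) and VEGFC, a growth factor of lymph vessels, by 1.15 (SE 0.19), each with an adjusted p of 0.0710. In the authors' deposited table for the NTS at 3 h, 11 genes are listed, 9 higher and 2 lower, among them HYAL2, TUBB6, VEGFC, THBD, VEGFA, NOS3 and ACVRL1. The authors' deposited table for the VRC at 3 h lists TUBB6 (adjusted p = 7.04e-05) and VEGFA, HYAL2 and THBD (adjusted p = 4.05e-04 each).

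**Figure D1:**
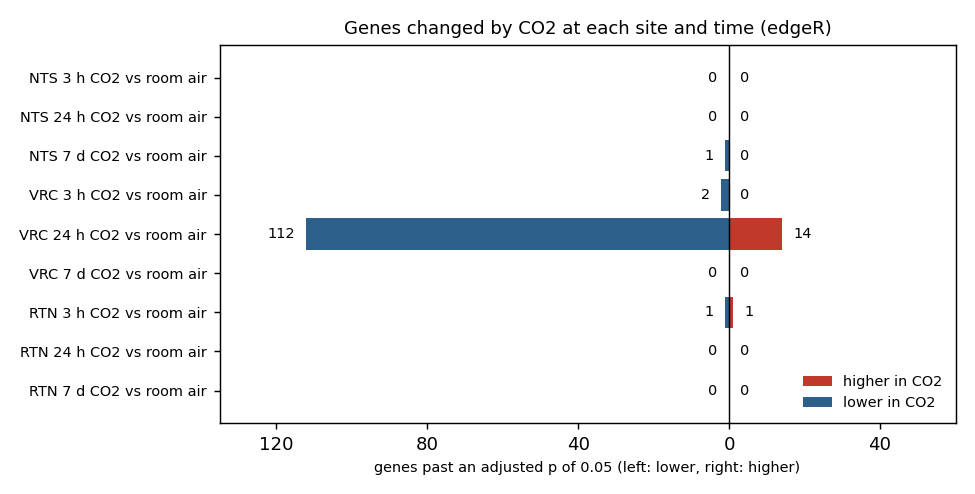
Genes past an adjusted p of 0.05 by edgeR in each of the 9 comparisons of CO2 with room air; bars to the left count genes lower in CO2 and bars to the right genes higher. The VRC at 24 h had 112 lower and 14 higher genes, and every other comparison had 2 or fewer.

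**Figure D2:**
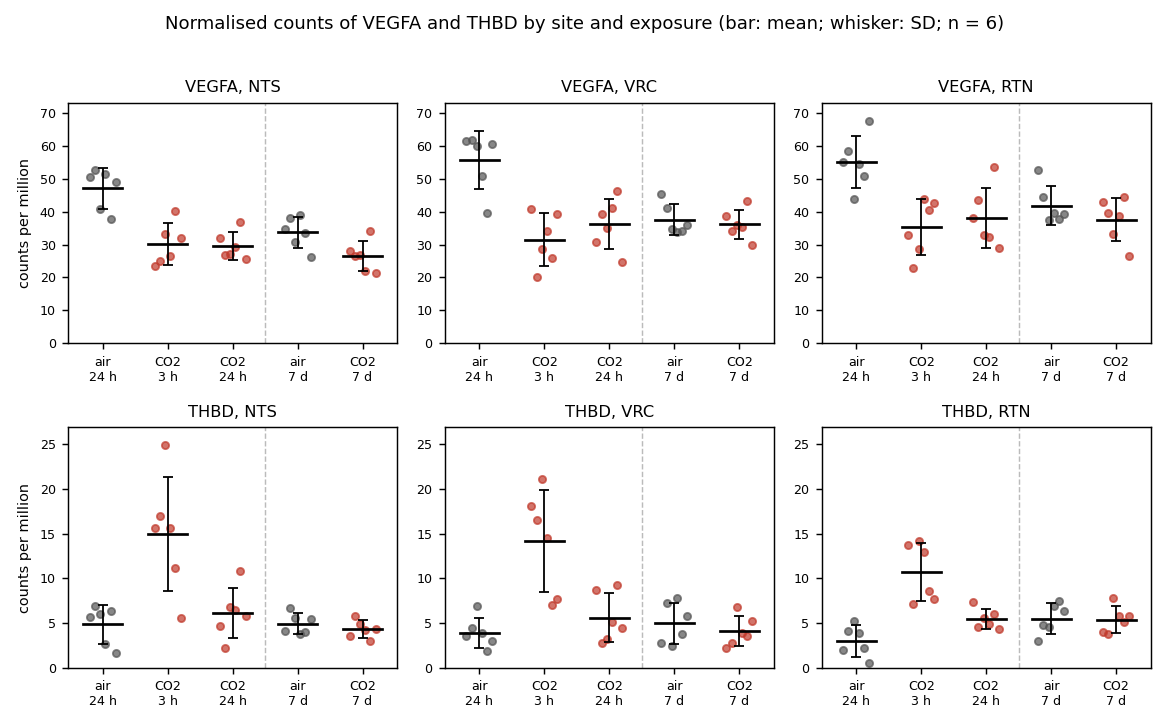
VEGFA and THBD in CPM (linear axis) by site and exposure; points are libraries, horizontal lines are means and whiskers are SD (n = 6), with room air in grey, CO2 in red and the batches parted by a dashed line. Mean VEGFA was lower after 3 h and 24 h of CO2 than in the 24 h room-air group at each site, and mean THBD was higher after 3 h.

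In the VRC at 3 h EGLN1 and VEGFB stayed past 0.05 whichever of the 12 libraries was left out. The call of EGLN1 ended in 2 of 11 other settings, with the libraries of the compared groups alone and with the likelihood ratio test over all 90 libraries (highest adjusted p 0.0523), and that of VEGFB in 0. The count ran from 2 to 180 (without number 3 of the 3 h group), with 78 without number 5 of room air and 4 without number 3 or 6 of room air. With the replicate number as a block, 95 genes passed in the VRC (20 higher, 75 lower) and 3 in the NTS. In the NTS the block made TUBB6, HYAL2 and ACVRL1 pass with log2 changes of 1.01, 0.90 and 0.99 (edgeR, adjusted p = 0.0367 each). The compared goats are different animals, and in the VRC residuals of the same number correlated between these groups at a median of 0.019. The number is thus not shown to pair the goats, and these counts are not a paired result. In the RTN, THBD passed in 4 of the 12 fits that leave out a library, and the count of 2 stayed only without number 6 of room air; it was 0 without number 2 or 4 of room air or number 1, 3, 4 or 5 of the 3 h group, and 1 without any other. In the RTN 0 genes also passed with the libraries of the compared groups alone, and estimateDisp with legacy=TRUE left only the fall of ENSCHIG00000022219.

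After 24 h of CO2, 126 of 15424 genes passed 0.05 by edgeR in the VRC, of which 112 fell and 14 rose; 71 carry a symbol. This was the highest count of the 9 CO2 comparisons by edgeR, but voom with quality weights called 164 here and 273 in the NTS at 24 h, and the likelihood ratio test over all 90 libraries 135 and 250. EGLN1 fell by 0.89 on the log2 scale (SE 0.13, adjusted p = 0.00762), from 79.3 ± 9.8 to 42.2 ± 3.3 CPM (SD, n = 6 each). PPM1D, a phosphatase of the DNA damage response, fell by 1.53 (SE 0.24) from 21.5 ± 4.5 to 7.37 ± 0.77 CPM, and NCK2, an adaptor of receptor tyrosine kinases, by 1.00 (SE 0.16) from 38.7 ± 6.1 to 18.8 ± 3.4 CPM. OLIG1, a transcription factor of oligodendrocytes, fell by 1.91 (SE 0.43, adjusted p = 0.0489), from 100.4 ± 12.7 to 26.1 ± 7.8 CPM, and NR1D2, a nuclear receptor of the circadian clock, by 0.83 (SE 0.19, adjusted p = 0.0357). Of the other genes that the rule names among the falling ones, DENND5A fell by 0.59, LRP3 by 0.81, RAB12 by 1.20, BTBD6 by 1.06, LRP8 by 1.02, SELENOO by 0.99, MTCL2 by 0.79, LEMD2 by 1.35 and CCDC85C by 1.38. CD1D, which presents lipid antigens, rose by 1.30 (SE 0.27, 2.53 ± 0.41 to 5.84 ± 2.96 CPM), NCF4, a subunit of the phagocyte NADPH oxidase, by 1.48, GUCA1A by 1.86 and M1AP by 0.67. Of 2 kinases chosen after their values were seen, STK11 fell by 0.96 and AKT1 by 1.20.

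OLIG1 averaged 27.4 ± 9.6 CPM in the VRC of the 7 d room-air goats, close to its 26.1 CPM after 24 h of CO2, and 37.1 ± 10.0 and 31.8 ± 12.2 CPM in the NTS and RTN of the 24 h room-air goats. EGLN1 averaged 35.7 ± 7.0 CPM in the VRC of the 7 d room-air goats. Leaving out numbers 1 to 5 of the CO2 group in turn gave 18, 81, 43, 52 and 24 genes, where number 4 is the library of 5.46 M counts, and leaving out numbers 1 to 4 of room air gave 53, 43, 30 and 61. Without any other library 111 to 126 genes passed. EGLN1, PPM1D, NCK2, DENND5A, LRP3, RAB12, BTBD6, LRP8, SELENOO, MTCL2 and STK11 passed in all 12 of these fits, LEMD2 and CCDC85C in 11, NR1D2 in 2 and OLIG1 in 0. Of the rising genes GUCA1A passed in 7, CD1D in 6, and M1AP and NCF4 in 2, and AKT1 passed in 3. The calls of NCF4 and OLIG1 also ended in 6 and 3 of 11 other settings, and that of GUCA1A in 2 of 10. Those of CD1D, M1AP, NR1D2 and AKT1 ended in 1 of 11 each. DESeq2 called 274 genes, edgeR with the libraries of the compared groups alone 263 and estimateDisp with legacy=TRUE 81.

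**Figure D3:**
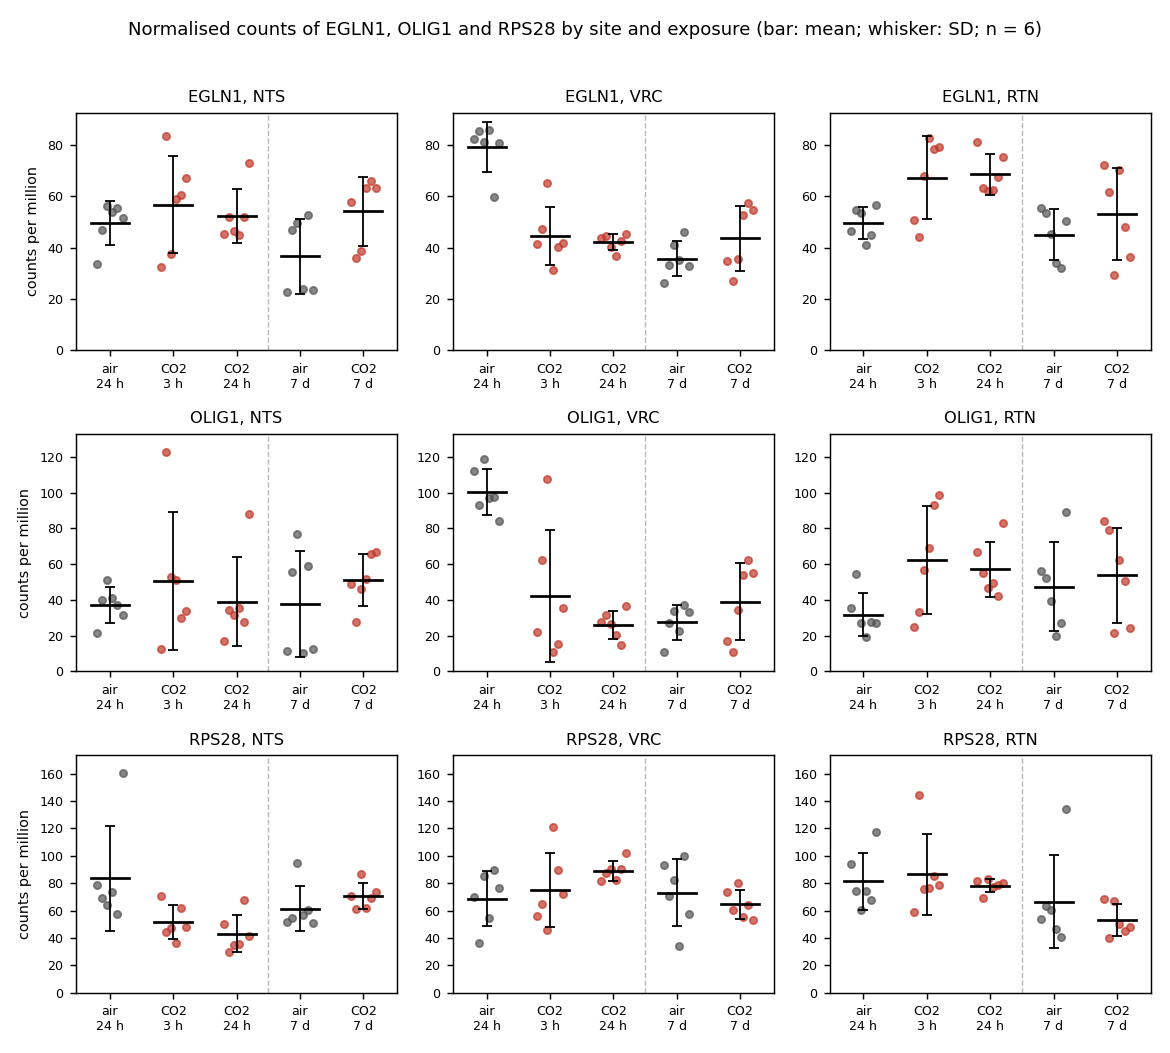
EGLN1, OLIG1 and RPS28 in CPM (linear axis) by site and exposure; points are libraries, horizontal lines are means and whiskers are SD (n = 6), with room air in grey, CO2 in red and the batches parted by a dashed line. OLIG1 averaged 100.4 CPM in the VRC of the 24 h room-air goats and 62.6 CPM or less in every other group, and RPS28 averaged 83.7 CPM in the NTS of room air and 43.3 CPM after 24 h of CO2.

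In the NTS after 24 h of CO2, RPS28, RPL38, NDUFA2 and UQCRQ had lower means than in room air, and none of the 4 passed 0.05 by edgeR with all libraries. They were chosen after their values were seen, from genes that the authors had selected on these libraries. RPS28 and RPL38, proteins of the small and large ribosomal subunits, averaged 83.7 ± 38.3 and 74.8 ± 25.4 CPM in room air and 43.3 ± 13.7 and 41.3 ± 13.4 CPM after CO2 (SD, n = 6 each). NDUFA2, of complex I, averaged 223.6 ± 45.3 and 151.0 ± 13.6 CPM, and UQCRQ, of complex III, 245.6 ± 53.0 and 162.7 ± 11.95 CPM. By edgeR with all libraries 0 of 15605 genes passed 0.05 (lowest adjusted p = 0.111), although 1591 had an unadjusted p under 0.05; DESeq2 called 191 genes and voom with quality weights 273. Without the 5 libraries that stood apart, a fit chosen after the data were seen, 148 genes passed, of which 132 were lower and 16 higher. In that fit RPS28 was lower by a log2 change of -0.88 (edgeR, adjusted p = 0.0190) and RPL38 by -0.87 (adjusted p = 0.00921). UQCRQ was lower by -0.58 and VEGFA by -0.79 (edgeR, adjusted p = 0.00443 each). With all libraries VEGFA did not pass 0.05 by edgeR. It came past it in 4 of 12 other settings, whose log2 changes ran from -0.79 to -0.61. The authors' deposited table for the NTS at 24 h lists 180 genes, 25 higher and 155 lower.

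Of the 29 lists fixed beforehand, 2 passed 0.05 by Fisher's exact test, both among the 155 genes that the authors' deposited table gives as lower in the NTS at 24 h. From the cytosolic ribosomal proteins, 5 of 51 members were there (RPS28, RPL11, RPL38, RPLP2 and RPL27) against 0.446 expected (Fisher's exact test, adjusted p = 0.0283 over 348 tests). From the nuclear-encoded genes of oxidative phosphorylation, 4 of 36 were there (UQCRQ, NDUFA2, COX6B1 and COX5B) against 0.315 expected (Fisher's exact test, adjusted p = 0.0463). The test takes genes as independent, whereas the ribosomal and respiratory-chain genes of this table varied together within other groups (SD of their median 0.246 against 0.0472 for matched random sets), a dependence the test does not allow for. Sets formed by symbol after the values were seen, without a test, hold 14 ribosomal protein genes and 11 NDUF, UQCR and COX genes that the authors' deposited table gives as lower; the second set holds the copper chaperone COX17 and leaves out COX1, which the authors' deposited table gives as higher. Their median log2 changes were -0.70 and -0.56 in the NTS, 0.37 and 0.29 in the VRC, and -0.06 and -0.11 in the RTN. Of single genes chosen after their values were seen, the mitochondrially encoded COX1 had a higher mean after CO2 in the NTS, with 322.2 ± 154.2 CPM in room air and 1040 ± 526.1 CPM after CO2 (log2 change 1.71, SE 0.63, adjusted p = 0.345). The neuronal genes PRPH, GRP and NPFF, chosen in the same way, had log2 changes of -3.94, -3.40 and -4.09 (edgeR, adjusted p = 0.476, 0.346 and 0.453). All 3 were highest in room-air library 6, 1 of the libraries that stood apart. AIF1, a microglial gene, differed by -0.64, the myeloid CD14 by 0.84, and the erythroid genes HBQ1 and HEMGN by -0.82 and 1.88 in the NTS. None passed 0.05 by edgeR with all libraries. HBQ1, CD14 and AIF1 came past it in 4, 2 and 1 of 12 other settings, and HEMGN in 1 of 11. Without the libraries that stood apart HBQ1 differed by -0.80 (edgeR, adjusted p = 0.0332). These 4 genes were also chosen after their values were seen.

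Lists other than those 2 gave no call. VEGFA and EGLN1 of the hypoxia-inducible list, OLIG1 and OLIG2 of the oligodendrocyte and myelin list, TTR of the ependymal and choroid plexus list, HEMGN and HBQ1 of the blood cell list, CD14 of the cytokine list, NR1D2 of the circadian clock list, GABRB2 of the GABA and glycine list, GRP of the neuropeptide list and AIF1 of the microglia list were the members found. The other 18 lists had 0 members among the entries that carry a symbol; 93 of the 342 deposited entries carry only an identifier and could not be matched to a list. These covered immediate early genes, glucocorticoid-responsive genes, carbonic anhydrases and acid-base transporters, CO2 and proton sensing, interferon-stimulated genes, antigen presentation and complement, the unfolded protein response and heat shock, cholesterol synthesis, lipid metabolism, glutamate receptors, monoamine and acetylcholine signalling, ion channels, synaptic genes, site markers, and markers of astrocytes, oligodendrocyte precursors, endothelium and pericytes, and meninges. Over the 9 comparisons, 4 values of linked list members passed over all genes and 54 adjusted over the list alone; the authors picked these members from the same libraries, so the second count is not independent evidence.

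In the RTN after 24 h of CO2, 0 of 15479 genes passed 0.05 by edgeR, with 1001 at an unadjusted p under 0.05; DESeq2 called 9 and voom with quality weights 0. VEGFA differed by -0.52 (SE 0.16, adjusted p = 0.533), with 55.1 ± 7.9 CPM in room air and 38.2 ± 9.1 CPM after CO2 (SD, n = 6 each). EGLN1 differed by 0.47 (SE 0.13) and VEGFB by 0.57 (SE 0.12) in the RTN, neither past 0.05, against falls of both in the VRC; these genes of the RTN were chosen after their values were seen. VEGFA in the VRC differed by -0.63 at 24 h (SE 0.16, adjusted p = 0.0769).

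A test of whether the CO2 effect differed between sites passed for 11 of 16339 genes at 3 h and for 313 at 24 h. Among genes with a symbol EGLN1 had the lowest p at both times (adjusted p = 0.0169 and 0.00325). Its effect in the VRC lay below that in the RTN by a log2 difference of -1.27 (SE 0.23) at 3 h and -1.37 (SE 0.23) at 24 h. Both times share the 24 h room-air libraries, and in those of the VRC EGLN1 averaged 79.3 CPM against 35.7 CPM at 7 d, so the values at 3 h and 24 h are not independent. VEGFB, RNF157, NRG2, UBP1, RDH10 and CCDC85C followed at 3 h, and PPM1D, SMIM11, DACT3, LATS2, PHLDA3, TRIM28, CCDC85C, ZNF329 and MYO1G at 24 h. PPM1D had log2 changes of 0.12, -1.53 and 0.68 in the NTS, VRC and RTN at 24 h, and TRIM28, a corepressor of transcription, 0.02, -0.98 and 0.41. With the goat as a block 107 and 647 genes passed, and DESeq2 called 74 at 3 h. At 7 d, 0 of 16050 genes passed by edgeR, 10 with the goat as a block and 4 by DESeq2. At an unadjusted p under 0.05 there were 761 genes, against 802.5 expected by chance.

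After 7 d of CO2, compared with goats kept 7 d in room air, the NTS had 1 gene past 0.05 of 15311. MAN2B1, the lysosomal alpha-mannosidase, fell by 0.80 on the log2 scale (SE 0.11, adjusted p = 0.0389), from 119.3 ± 17.9 to 68.4 ± 8.5 CPM (SD, n = 6 each). Its other group means lay between 68.1 CPM in the VRC after 3 h and 91.8 CPM in the RTN after 24 h, so the room-air group of the NTS at 7 d was the highest of the 15. MAN2B1 passed in 4 of the 12 fits without a library, the count was 3 without number 3 of room air and 0 without number 4 or 5 of room air or number 2, 4, 5 or 6 of CO2, and with the replicate number as a block 0 genes passed. DESeq2 called 75 genes and the authors' deposited table lists 22, 14 higher and 8 lower, among them DHX30, a mitochondrial RNA helicase. Here DHX30, chosen for this time after its values were seen, differed by -0.55 (SE 0.09, adjusted p = 0.141). The VRC had 0 of 15179 genes past 0.05 and the RTN 0 of 15326. At an unadjusted p under 0.05 there were 996 and 499, against 759 and 766 expected by chance. DESeq2 called 2 genes at each and voom with quality weights 0. VEGFA, chosen after its values were seen, differed by -0.35, -0.05 and -0.16 at the NTS, VRC and RTN at 7 d (SE 0.13, 0.10 and 0.13).

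Whether the effect at 7 d differed from that at 24 h was tested as an interaction, since time and batch differ between the groups but each effect is taken within its batch. In the NTS 72 of 16047 genes passed, 56 with a higher and 16 with a lower effect at 7 d. The respiratory-chain genes NDUFA2 and UQCRQ had differences of 0.76 (SE 0.14) and 0.77 (SE 0.15), each with an adjusted p of 0.0316: NDUFA2 had a log2 change of -0.56 at 24 h and 0.18 at 7 d. POLR2I, a subunit of RNA polymerase II, MICOS10, of the mitochondrial inner membrane, and FAM241B had differences of 0.86, 0.82 and 0.73. ACVRL1 had a difference of -1.20 (SE 0.23), with log2 changes of 0.58 at 24 h and -0.64 at 7 d. MAN2B1, DHX30 and TNFAIP1 had differences of -0.86, -0.60 and -0.79. Leaving out single libraries gave 0 genes (without number 3, 4 or 6 of 24 h CO2, 1, 2 or 4 of 7 d room air, or 2, 3, 5 or 6 of 7 d CO2) to 251 (without number 3 of 7 d room air). It gave 158 without number 5 of 24 h CO2, 151 and 4 without numbers 5 and 6 of 24 h room air, and a count within 1.5 times the 72 for 4 libraries. NDUFA2 and POLR2I passed in 14 of these 24 fits, ACVRL1 and MAN2B1 in 13, UQCRQ, MICOS10 and FAM241B in 11, DHX30 in 8 and TNFAIP1 in 5. The calls of TNFAIP1 and DHX30 also ended in 2 and 1 of 6 other settings (highest adjusted p 0.0602). The block gave 223 and the fit without the libraries that stood apart 126. In the VRC and RTN 0 genes passed by edgeR, and DESeq2 called 49 and 0. At an unadjusted p under 0.05 there were 1059 and 514, against 788 and 794 expected by chance. The block gave 24 in the VRC.

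Between 24 h and 3 h of CO2, 0 genes passed by edgeR at any site, with 1776, 1087 and 1390 genes at an unadjusted p under 0.05 in the NTS, VRC and RTN. DESeq2 called 15, 14 and 25 genes, and the block gave 48 in the NTS. THBD, chosen after its values were seen, averaged 15 ± 6.4, 14.2 ± 5.7 and 10.8 ± 3.2 CPM after 3 h in the NTS, VRC and RTN and 6.11 ± 2.83, 5.60 ± 2.76 and 5.46 ± 1.13 CPM after 24 h (SD, n = 6 each). TTR, the transthyretin made by choroid plexus and chosen in the same way, had a log2 change of 6.96 (SE 1.96, adjusted p = 0.420) in the RTN at 3 h, where 1 library held 1905 CPM and the other 5 between 0.957 and 3.25 CPM.

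In room air the sites themselves differed. The 3 genes named here, SHOX2, MEOX2 and ACKR1, were chosen after their values were seen. SHOX2, a homeobox gene, differed at each pair of sites in both room-air groups and was highest in the RTN. It averaged 1.87 ± 2.54, 7.17 ± 1.85 and 37.6 ± 14.7 CPM in the NTS, VRC and RTN at 24 h and 0.394 ± 0.542, 6.50 ± 1.35 and 18.2 ± 6.2 CPM at 7 d (SD, n = 6 each). NTS and RTN differed by -4.27 (SE 0.52) at 24 h and -5.48 (SE 0.41) at 7 d for SHOX2. Between NTS and VRC at 24 h SHOX2 differed by -1.88 (SE 0.58, adjusted p = 0.0443), a difference that was not past 0.05 by DESeq2 or with no filter on low counts. Without the 5 NTS libraries that stood apart, the SHOX2 differences at 24 h were -4.63 between NTS and VRC (adjusted p = 8.17e-05) and -7.00 between NTS and RTN. Between VRC and RTN at 7 d SHOX2 was not past 0.05 by DESeq2 (adjusted p = 0.144). MEOX2, a homeobox gene of vessels, was lower in the NTS than in the VRC by log2 changes of -2.15 and -2.56, and ACKR1, a venular chemokine receptor, lower in the NTS than in the RTN by -1.49 and -1.17. Past 0.05 were 1764 genes between NTS and VRC at 24 h (886 higher in the NTS), 515 between NTS and RTN (262 higher in the NTS) and 845 between VRC and RTN (394 higher in the VRC). At 7 d there were 1359 (736 higher), 1289 (588 higher) and 704 (245 higher). Of the genes past 0.05 in both room-air groups, 723, 294 and 244 were shared for NTS and VRC, NTS and RTN, and VRC and RTN, against 153, 42.3 and 38.1 expected by chance, and 723, 294 and 243 kept their direction. With the goat as a block the counts were 2767, 1132 and 2020 at 24 h and 2625, 2371 and 1979 at 7 d. DESeq2 called 847 genes between NTS and RTN and 1438 between VRC and RTN at 24 h, where the fit without the NTS libraries that stood apart gave 946 and 1849.

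Set against the authors' deposited tables, which list 342 entries over the 9 comparisons, 323 were tested here and all 323 had the same direction. An unadjusted p under 0.05 was found for 316 of them and an adjusted p under 0.05 for 81, and 110 passed 0.1. The entries come from these same counts and were selected by the authors, and symbols were linked only where fold changes were alike. The shared direction is therefore not independent evidence. The deposited tables hold 0 genes for the RTN at 24 h and 7 d and for the VRC at 7 d. For the VRC at 24 h the authors' deposited table lists 115 genes, 20 higher and 95 lower. The deposited counts leave out absolute log2 changes under 0.5, so they are not like for like with the counts here. In the likelihood ratio fit over all 90 libraries 250 genes of the NTS at 24 h passed 0.05, and 180 with that limit.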

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

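The tests of explanations in this part, the divisions of the libraries, and the fits without single libraries or sets of libraries were chosen after the results were seen; the comparisons were planned. A library counted as far from its group when its gap to the nearest of the other 5 exceeded Dixon's critical share of the range of the 6. This held for 18 of 147 pairs of a named gene and a group and for 3 of 15 groups by total counts, and chance gives about 1 in 20.

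Several of these were neuronal, ribosomal and respiratory-chain genes of the NTS. Room-air library 6 of the NTS at 24 h held 160 CPM of RPS28 (57.2 to 78.3 in the other 5), 124 CPM of RPL38 (50.5 to 72.2) and 315 CPM of NDUFA2 (194 to 213). It also held 569.6 CPM of PRPH (3.58 to 214), 49.8 CPM of GRP (0.384 to 7.10) and 46.7 CPM of NPFF (0.215 to 9.35). Library 5 of the NTS after 24 h of CO2 held 67.3 CPM of RPL38 (30.9 to 42.7), 35.5 CPM of PRPH (1.90 to 4.92), 0.815 CPM of SHOX2 (0 to 0.28), 15.8 CPM of HBQ1 (6.85 to 8.78) and 85.8 CPM of ACKR1 (2.43 to 32.8). HEMGN was at 1.15 CPM in room-air library 1 of the NTS (0.143 to 0.512). In the VRC, EGLN1 was at 59.8 CPM in room-air library 5 (80.8 to 85.8) and MTCL2 at 69.5 CPM in room-air library 1 (47.2 to 49.0). After 24 h of CO2 library 5 of the VRC held 3.98 CPM of GUCA1A (0.73 to 1.93) and 389.8 CPM of COX1 (217 to 247), and library 3 held 163 CPM of TTR (1.39 to 20.6). TTR reached 1905 CPM in library 4 of the RTN after 3 h of CO2 (0.957 to 3.25). Total counts stood apart in library 3 of the NTS after 3 h (9.64 M, 19.5 to 25.0 M in the others), library 4 of the VRC after 24 h (5.46 M, 19.3 to 24.2 M) and library 2 of the NTS after 7 d of CO2 (36.8 M, 20.3 to 26.0 M).

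Other results stood out because the CO2 effect differed between times or sites by a test of that difference (edgeR). Between 24 h and 7 d in the NTS the adjusted p was 0.0316 for NDUFA2, ACVRL1, POLR2I, UQCRQ and MICOS10, 0.0318 for FAM241B and MAN2B1, 0.0377 for DHX30 and 0.0435 for TNFAIP1. Between the sites at 3 h it was 0.0169 for EGLN1 and VEGFB and 0.0359 for RNF157, NRG2, UBP1, RDH10 and CCDC85C. Between the sites at 24 h it was 0.00325 for EGLN1 and PPM1D, 0.00520 for SMIM11, DACT3 and LATS2, 0.00594 for PHLDA3 and TRIM28, and 0.00678 for CCDC85C, ZNF329 and MYO1G.

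The first pattern weighed is the fall of 112 genes, EGLN1, PPM1D and OLIG1 among them, in the VRC after 24 h of CO2. Of these, 94 had their highest mean of the 15 groups in the VRC room-air libraries of 24 h. Of all 16630 genes, 1393 did. The set was picked by a comparison with those libraries, which favours such a count. Without library 4, which is of low depth, the median log2 change was 0.972 of that with it, and 112 of 112 genes were still lower. These genes were picked in a fit that holds the remaining libraries, which favours both values. Without library 4, and so with fewer samples, 43 genes passed as lower. The kept median argues only against low depth of library 4 as the whole cause. The excess of the VRC room-air libraries over the other room-air groups was 0.845 of the CO2 effect, measured in room-air libraries not used to rank the genes (0.752 to 0.985 over 20 divisions), which is consistent with room-air libraries of this site that stand apart. The set's median also varied within the other groups more than in 100 percent of 1000 matched random sets (SD 0.298 against a median of 0.0287), so a state that varies between libraries of any group stays open. A CO2 effect particular to the VRC stays open too, since the design holds no second room-air group of that time and batch.

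The second pattern is the lower ribosomal and respiratory-chain transcripts, such as RPS28 and NDUFA2, in the NTS after 24 h of CO2. For 25 such genes the median log2 change without the NTS libraries that stood apart was 0.926 of that with them. These genes, which leave out COX1, were taken by symbol from those the authors' deposited table gives as lower. The authors had selected them on libraries that include the ones kept, which favours such a ratio. It thus argues only against the libraries that stood apart as the sole cause. For the median of PRPH, GRP and NPFF the same ratio was 0.111, which is the value of PRPH, so its low value may come from these libraries. NPFF turned from -4.09 to 0.17, and GRP kept a lower value, -1.23 against -3.40. The medians at the other sites averaged -0.211 of the NTS median, with -0.66 in the NTS, 0.36 in the VRC and -0.08 in the RTN. The VRC value is measured against room-air libraries that may stand apart. A shift of whole goats, of like size at each site, is thus argued against by the RTN only. The genes were selected on the NTS, which favours a smaller value elsewhere. The 25 genes varied together within other groups more than 100 percent of 1000 matched random sets (SD 0.246 against 0.0472), so a variation shared by these genes in any group stays open beside an effect of CO2 on the NTS.

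The third pattern is VEGFA, whose means were lower at all 3 sites after 3 h and 24 h of CO2, a gene chosen for these values. Whether all hypoxia-inducible genes fell at each site could not be decided, since only 2 genes of that list carry a linked symbol. Of these, EGLN1 had a higher mean in the RTN at 24 h by 0.47 (SE 0.13). It was chosen after its values were seen and did not pass the threshold by edgeR. The tests of 10 other settings gave it adjusted p of 0.189 to 0.762. The unequal time of the 3 h group and its room-air group is argued against by the 24 h group of equal time, whose mean over goats and sites lay only 0.108 above that of the 3 h group. The same mean after 24 h of CO2 lay -0.136 from the 7 d room-air goats, which is consistent with high VEGFA in the 24 h room-air goats, but those groups also differ in batch. A CO2 effect and room-air goats that stand apart cannot be separated with these groups.

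Each count was compared with 100 divisions of the libraries into groups of equal sizes, the real one included. Chance is argued against for the VRC at 24 h, where 126 genes passed and only the real division reached that count (highest other 5). Leaving out single libraries there gave 18 to 126 genes, and 100 divisions can give no share below 1 in 100. Chance is therefore not firmly excluded for this count among 24 results. It is also argued against for the site difference at 24 h (313, 1 division, highest other 1, and with the goat as a block 647, 1 division, highest other 2). That difference uses the same VRC room-air libraries, so it is not separate evidence. For the site pairs in room air chance is argued against too, each count being reached by 1 division. Between NTS and VRC 1764 genes passed at 24 h (highest other 73) and 1359 at 7 d (highest other 3). Between NTS and RTN it was 515 (highest other 161) and 1289 (highest other 55). Between VRC and RTN it was 845 (highest other 13) and 704 (highest other 85). For the NTS difference between 7 d and 24 h 72 genes passed and 1 division reached that count (highest other 2). Leaving out single libraries there gave 0 to 251 genes, and NDUFA2 passed in 14 of 24 such fits. Chance is therefore not firmly excluded for it. For the RTN at 3 h 2 genes passed and 4 divisions reached that count (highest other 921), a narrow margin among 24 results judged this way. THBD passed there in 4 of 12 fits without a library, so chance is not firmly excluded there either. Chance cannot be excluded for the NTS at 7 d (1 gene, 5 divisions, highest other 40), the VRC at 3 h (2 genes, 7 divisions, highest other 486) and the site difference at 3 h (11 genes, 9 divisions, highest other 1106; with the goat as a block 107 genes, again 9 divisions, highest other 2263). For each count of 0, all 100 divisions reached it, and the highest others were 947 in the NTS at 3 h, 2 in the NTS at 24 h, 937 in the VRC at 7 d, 2 and 34 in the RTN at 24 h and 7 d, 1, 3 and 3 between 24 h and 3 h in the NTS, VRC and RTN, 790 and 2 for the later difference in the VRC and RTN, and 1 for the site difference at 7 d. With the goat as a block that last difference had 10 genes, a count that 2 of the 100 divisions reached (highest other 103). In the NTS at 3 h the 31 other divisions that part all 6 numbers gave 0 genes at most, as the real one did. The 947 thus come from a division that keeps numbers together. With the replicate number as a block, 3 genes passed there and 1 of these 32 divisions, the real one, reached that count (highest other 1). As the number is not shown to mark pairs, chance is not excluded by this count.

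Divisions that call many times the real count point to a structure of the samples. At 3 h 1 exchange, of room-air goats 5 and 6 with 3 h goats 1 and 3, gave the highest count at each site (947, 486 and 921 genes) and for the site difference (1106). It leaves numbers 5 and 6 of both groups, which vary together in the NTS, on the same side, with 3 h goats 2 and 4. Of its genes 49 were shared between NTS and VRC, 137 between NTS and RTN and 87 between VRC and RTN, so which libraries give the counts was not resolved. At 7 d an exchange of CO2 goats 1 and 3 with room-air goats 4 and 6 gave the 937 genes in the VRC and the 40 in the NTS.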

How the results depend on the processing

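Fits without sets of libraries or single libraries and the likelihood ratio test over all 90 libraries were chosen after the data were seen; the other settings were planned. Of the values of named genes under the alternatives, 963 kept direction and side of the threshold, 101 came past it, 31 no longer did and 2 turned direction. RLE factors and a filter of 1 CPM moved no count by more than 1.5 times. Of the counts under all settings 133 stayed within 1.5 times and 111 did not; the cause was not tested unless stated. The estimated correlation and the replicate block for the gene lists were not run, as the competitive test of the lists was not.

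DESeq2 gave 12, 191 and 75 genes in the NTS at 3 h, 24 h and 7 d, 121, 274 and 2 in the VRC, and 17, 9 and 2 in the RTN. Between 24 h and 3 h of CO2 it gave 15, 14 and 25 in the NTS, VRC and RTN, for the 7 d less the 24 h effect 302 in the NTS and 49 in the VRC, and for the site difference 74 at 3 h and 4 at 7 d. In room air it gave 847 between NTS and RTN at 24 h, and 1438 and 1123 between VRC and RTN at 24 h and 7 d. Voom with quality weights gave 1, 273 and 2 in the NTS at 3 h, 24 h and 7 d, 44 in the VRC at 3 h and 0 in the RTN at 3 h. With 1 surrogate variable there were 3 in the NTS and 4 in the VRC at 3 h. The likelihood ratio test gave 11, 250 and 34 in the NTS at 3 h, 24 h and 7 d and 15 in the VRC at 3 h. With legacy=TRUE there were 81 in the VRC at 24 h and 1 in the RTN at 3 h. With no filter the 72 of the NTS became 45. With other libraries in the fit there were 2 in the NTS at 7 d, 263 in the VRC at 24 h and 0 in the RTN at 3 h.

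The replicate number as a block gave 3, 13 and 0 in the NTS at 3 h, 24 h and 7 d, 95 in the VRC at 3 h, 48 in the NTS between 24 h and 3 h, 223 in the NTS and 24 in the VRC for the 7 d less the 24 h effect, and 107, 647 and 10 for the site difference at 3 h, 24 h and 7 d. In room air it gave 2767 and 2625 between NTS and VRC at 24 h and 7 d. It gave 1132 and 2371 between NTS and RTN, and 2020 and 1979 between VRC and RTN. Across sites the number is the goat, so this block removes differences between goats. Between exposures within a site the goats are different animals, and the number is not shown to pair them.

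Without the 5 NTS libraries that stood apart there were 5 genes in the NTS at 3 h, 148 at 24 h, 2 between 24 h and 3 h, 126 for the 7 d less the 24 h effect, and in room air at 24 h 946 between NTS and RTN and 1849 between VRC and RTN; the last compares no NTS library, so there the removal acts through the variance of the fit. Without the 2 shallow libraries 52 passed in the VRC at 24 h, with fewer samples, and without the library of highest TTR 0 in the RTN at 3 h. NPFF in the NTS at 24 h turned from -4.09 to 0.17 without the libraries that stood apart, and TTR in the RTN at 3 h from 6.96 to -0.23 without its highest library; both values rest on the libraries removed. Leaving out single libraries gave 0 to 3 genes in the NTS at 7 d, 2 to 180 in the VRC at 3 h, 18 to 126 in the VRC at 24 h, 0 to 2 in the RTN at 3 h and 0 to 251 for the NTS difference between 7 d and 24 h.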

Other observations

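The gene in this part was chosen after its values were seen. The mitochondrial COX1 had means in opposite order at 2 sites. It averaged 322.2, 585.8 and 1040 CPM in the NTS in room air and after 3 h and 24 h of CO2, and 911, 667 and 257 CPM in the VRC. The log2 change at 24 h was 1.71 in the NTS and -1.81 in the VRC, with adjusted p of 0.345 and 0.0818 by edgeR, and the test of COX1 between the sites gave an adjusted p of 0.0202 by edgeR. COX1 came past 0.05 in 1 of 12 other settings in the NTS and in 3 of 11 in the VRC, with DESeq2 at 0.00550 there. The authors' deposited tables list COX1 at both sites (adjusted p = 0.0375 and 0.0297).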
